A study of Mus musculus with 14 samples.

How the data were processed

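RNA was measured by sequencing in 14 libraries of long-term hematopoietic stem cells (LT-HSCs) from female C57BL/6 mice. Per the labels' protocols, bone marrow cells negative for lineage markers and CD48 and positive for Sca-1, c-Kit and CD150 were sorted, cDNA was made from 5000 cells by template switching, and libraries were made by tagmentation. Per the labels, 4 libraries held cells with low and 4 held cells with high surface P-selectin (Selp) from 4 mice older than 24 months. The other 6 held donor-derived cells sorted 16 weeks after 1000 Selp low or Selp high cells were given to irradiated recipients aged 10 to 16 weeks, 3 libraries for each input. The cells sorted after transplantation were gated on CD45.2 and not on P-selectin.

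The deposited counts are whole numbers of reads per gene for 55450 gene identifiers, which the authors made with STAR 2.7.0d on GRCm38, per the submitters' processing notes, which also name FastQC 0.11.9 and Picard 2.23.0. The annotation release and the counting settings are not given in the sources used here. All 55450 versioned identifiers matched the GENCODE annotation used for symbols and positions. The file's counts made without regard to strand were used, because the sums of the counts by strand had a ratio of 0.989 to 0.999 in every library, so a gene and an overlapping or antisense gene cannot be told apart. Unmapped, multimapping, unassigned and ambiguous reads stayed out of library sizes and tests and made up 3.35 to 5.06%, 9.93 to 13.4%, 3.37 to 5.13% and 4.20 to 4.79% of reads.

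Between 22374794 and 38216775 reads per library were assigned to genes. Counts were tested with edgeR 4.0.16 (R 4.3.3) with TMM factors, which ran from 0.963 to 1.042, and its quasi-likelihood test on a fit of 4 group means over all 14 libraries, with 10 residual degrees of freedom. Genes were kept by edgeR's expression filter with a minimum count of 10, which left 16878 genes. The biological coefficient of variation was 0.322. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM, which is counts relative to library size after TMM scaling as edgeR gives them, and log2 CPM values carry a prior count of 2. Fold changes are given with the standard error (SE) of the fit.

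Comparisons were Selp high against Selp low before transplantation, Selp high-derived against Selp low-derived cells after it, the difference of these differences, and post-transplant against pre-transplant libraries as the mean of both groups of each stage. The design, tests, alternatives, gene lists and the rule for naming genes were set before the data were examined. The rule takes Selp and the sort markers, up to 10 protein-coding genes with the largest change in each direction among called genes with a mean log2 CPM of at least 1 and no overlap of the groups, and for each list up to 4 members with the smallest p and 2 with the highest expression.

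The 27 lists of biology and gene families covered HSC ageing genes, long-term HSC, multipotent progenitor, lymphoid, myeloid and erythroid priming, megakaryocyte and platelet, platelet-restricted, S phase, G2 and M phase, quiescence, immediate early, NF-kB, heat shock, unfolded protein response, type I interferon, interferon gamma and MHC, p53 targets, cholesterol synthesis, glycolysis, detoxification, adhesion, epigenetic regulators, ribosomal proteins, nuclear OXPHOS, mitochondrially encoded and histone genes. The 11 marker lists covered other cell types. Selp was left out of all of them. Lists were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment within the 27 or the 11 lists. In the results a p called estimated is the adjusted p of camera with an estimated correlation. Camera with an estimated correlation, fry, and two-sided exact permutation tests of list means were run beside it. With 4 libraries against 4 the smallest exact p is 0.0286, or 0.125 with libraries exchanged within each of the 4 mice only, and with 3 against 3 it is 0.100.

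The replicate numbers of the pre-transplant libraries were checked for pairing. Deviations from the group means correlated with r of 0.29 to 0.53 across genes between same-numbered libraries and -0.40 to 0.05 between others, so a number was taken as a mouse. After transplantation same-numbered libraries had r of -0.05 to 0.02 and were not paired. No 2 libraries of a group agreed within sampling noise. P-values cover the spread between these libraries, and whether each post-transplant library came from a separate recipient is not given in the sources used here.

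The fit and list tests were tested on simulated data with 200 changed genes, drawn from those with a mean log2 CPM of at least 1. The HSC ageing list was shifted by 0.3 on the log2 scale as well, and its genes were not counted as false calls. That list was called in each comparison, also with an estimated correlation, and 0 of the 26 other lists were. In the simulated comparison before transplantation (16472 genes), 71 of 100 genes changed 2-fold and 97 of 100 changed 4-fold were called, with 2.86% of 175 calls false. After transplantation (16477 genes) the values were 62 and 94 of 100, with 4.29% of 163 calls false, and between the stages (16461 genes) 71 and 98 of 100, with 3.93% of 178 calls false. Simulated genes varied independently of each other, unlike real genes. Where fewer than these 200 genes differ, the adjusted threshold is stricter, so the shares called can be lower.

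Alternatives were other size factors, library totals alone, no filter, a stricter filter, DESeq2 1.42.0, limma voom with quality weights, a replicate block, only the libraries of the groups compared, and each library left out in turn. Added after seeing the data were a block before transplantation only, that block with only the pre-transplant libraries, a block with an estimated correlation, exact permutation tests of list means, the libraries of mouse 4 left out, the 2 post-transplant libraries that stood apart left out, and sets of 100 genes for persistence.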

Results

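The data were RNA-seq counts of LT-HSCs, the bone marrow cells that rebuild blood over the long term, from old mice. Cells were sorted by surface P-selectin, an adhesion receptor best known from activated platelets and endothelium, into a Selp low group (4 libraries) and a Selp high group (4 libraries) from 4 mice. Donor-derived LT-HSCs recovered from irradiated young recipients 16 weeks later made up a Selp low-derived group (3 libraries) and a Selp high-derived group (3 libraries). Reads assigned to genes numbered 26513095 to 38216775 in Selp low, 25972480 to 29305598 in Selp high, 22374794 to 27448409 in Selp low-derived and 23469262 to 29226370 in Selp high-derived libraries.

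Libraries parted first by stage. Principal component 1 held 33.3% of the variance and had scores of 29.0 to 55.2 before and -77.0 to -46.8 after transplantation. Component 2 (15.1%) set apart both libraries of mouse 4 (59.2 and 54.5) and Selp low-derived replicate 2 (60.5). The latter and Selp high-derived replicate 1 stood apart from the other post-transplant libraries, at -81.2 on component 3 (9.7%) and -71.0 on component 4 (7.6%). Both libraries of mouse 4 and Selp low-derived replicate 2 also had the highest list means of neutrophil markers, at 9.08, 9.44 and 8.59 log2 CPM, against 3.18 to 7.59 in the other 11. S100a8, a calprotectin subunit abundant in neutrophils, reached 3161, 4493 and 3224 CPM in them, against 50.8 to 1025 CPM elsewhere. The sort excluded cells stained for Gr-1 and Mac-1, which neutrophils carry.

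The comparison before transplantation asked how old LT-HSCs with much P-selectin differ from those with little. Selp (ENSMUSG00000026580.16, chromosome 1, 164115264 to 164150026, plus strand, GRCm38) was measured at 701 ± 73.4 CPM in Selp high (SD, n = 4) and 566 ± 96.7 CPM in Selp low cells (SD, n = 4). It was higher in Selp high cells in 4 of 4 mice, by 0.31 ± 0.12 on the log2 scale (SE), with an edgeR adjusted p of 0.957. Of the other sort markers, Slamf1, the gene of CD150, differed by 0.24 ± 0.12 and Kit by -0.19 ± 0.14, neither called. As a list, genes known to be higher in old than in young HSCs were higher in Selp high cells, and cell cycle and multipotent progenitor genes were lower, by camera with a preset correlation, with an adjusted p of 0.723 for each of these lists with an estimated correlation. In the main edgeR fit no single gene passed the threshold.

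**Figure D1:**
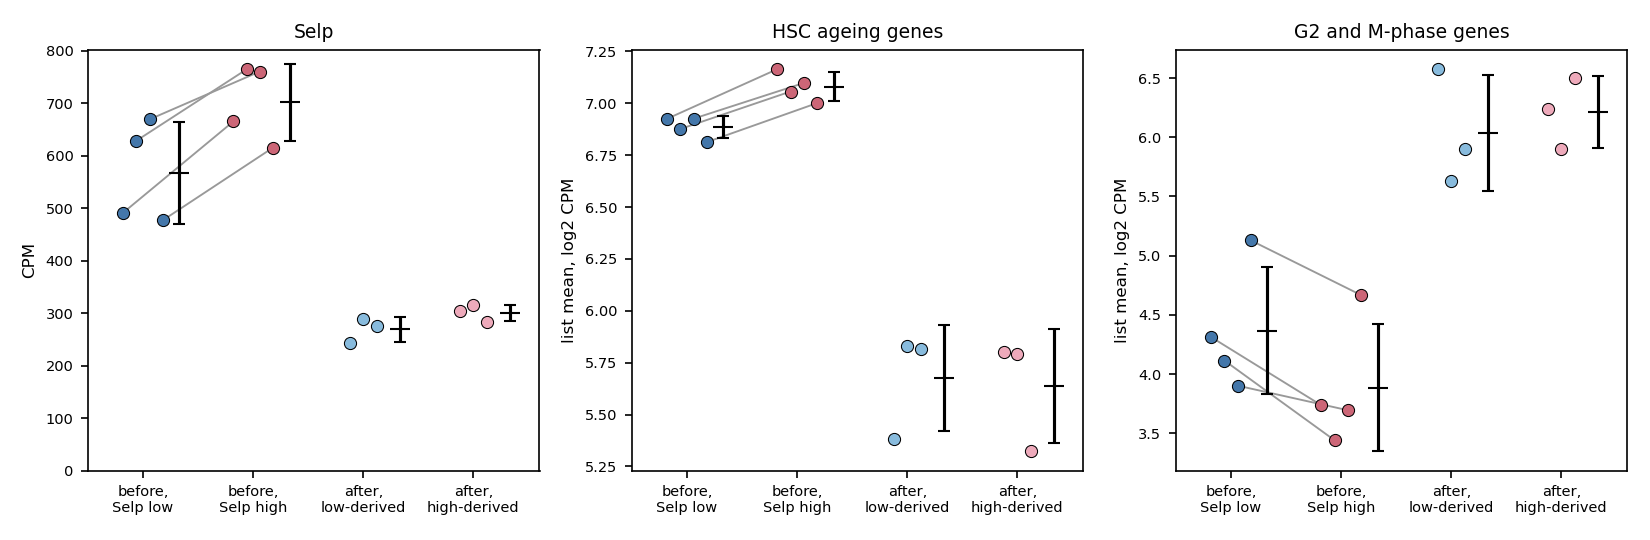
Selp in CPM (left), and list means in log2 CPM of HSC ageing genes (middle) and G2 and M-phase genes (right), for each library (points) of the 4 groups, with group mean and SD (bars) and lines joining libraries of the same mouse before transplantation. Selp averaged 566 and 701 CPM before and 269 and 301 CPM after transplantation.

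Of 49 measured HSC ageing genes, 40 had higher values in Selp high cells (median log2 change 0.15, camera adjusted p = 1.5e-06, adjusted p = 0.723 with an estimated correlation). The list mean was 7.08 ± 0.07 against 6.89 ± 0.05 log2 CPM (SD, n = 4 each, exact permutation p = 0.0286 with the 8 libraries exchanged freely, adjusted p = 0.771), and was higher in 4 of 4 mice. With libraries exchanged within each mouse only, the exact permutation p was 0.125, the smallest that 4 mice can give. Jam2, a junctional adhesion molecule, was at 301 ± 37.0 CPM in Selp high and 171 ± 4.76 CPM in Selp low cells, and the NAD-consuming surface enzyme gene Cd38 at 119 ± 16.6 and 78.1 ± 4.60 CPM. Mllt3, a regulator of HSC maintenance, was at 352 ± 28.6 and 244 ± 9.92 CPM, and Oxr1, an oxidation resistance gene, at 488 ± 36.1 and 386 ± 43.6 CPM. The abundant members Mmrn1 and Vwf, both of platelet granules, differed by 0.15 ± 0.14 and 0.15 ± 0.25 on the log2 scale. By edgeR none of these 6 genes was called over all genes, while DESeq2 called Jam2 (adjusted p = 0.0147). Adjusted over the list alone, edgeR called 1 of the 49 genes, and over all genes 0.

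Of 38 G2 and M-phase genes, 34 had lower values in Selp high cells (median -0.52, camera adjusted p = 1.3e-10), as did 29 of 34 S-phase genes (median -0.33, 1.3e-08) and 27 of 34 histone genes (median -0.39, 6.4e-04). With an estimated correlation the adjusted p was 0.723 for each of these lists. Plk1, a mitotic kinase, was at 11.8 ± 4.84 CPM in Selp high and 24.9 ± 11.9 CPM in Selp low cells, and the microtubule depolymerase gene Kif2c at 7.38 ± 2.35 and 14.2 ± 6.12 CPM. Cdt1, a replication licensing factor, was at 22.7 ± 3.14 and 35.4 ± 7.23 CPM, and the helicase subunit gene Mcm7 at 131 ± 23.4 and 187 ± 18.6 CPM. Counts of histone genes are uncertain, since the copies share sequence and replication-dependent histone transcripts mostly lack poly(A) tails. Without Selp low replicate 4 the G2 and M median was -0.12 (adjusted p = 0.0790) and the S-phase median -0.16 (0.0515), and without both libraries of mouse 4 they were -0.52 (4.9e-13) and -0.36 (4.9e-09). Without Selp high replicate 4 they were -0.87 and -0.50. The G2 and M list mean was lower in Selp high cells in 4 of 4 mice, and both libraries of mouse 4 had the highest values, at 5.13 and 4.67 against 3.44 to 4.31 log2 CPM in the other 6.

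Of 20 multipotent progenitor genes, 17 had lower values in Selp high cells (median -0.36, camera adjusted p = 2.2e-05, adjusted p = 0.723 with an estimated correlation). By edgeR 2 were called adjusted over the list alone and 0 over all genes, while DESeq2 called Myc over all genes (adjusted p = 3.9e-04). Myc, a growth regulator, was at 257 ± 45.9 CPM in Selp high and 429 ± 28.5 CPM in Selp low cells (log2 change -0.74 ± 0.13), and the receptor gene Flt3 at 8.33 ± 2.49 and 18.0 ± 8.83 CPM. Cdk6, a G1 kinase, was at 42.7 ± 15.7 and 70.9 ± 27.9 CPM. Sox4, a transcription factor of the lymphoid priming list, was at 90.6 ± 21.4 and 161 ± 14.8 CPM. Lymphoid priming genes had a median of -0.19 (camera adjusted p = 0.0451, 0.723 estimated) and myeloid priming genes of -0.30 (0.0150, 0.811 estimated). Without Selp low replicate 4 these medians were 0.01 and 0.18, and that of the multipotent progenitor genes was -0.12 (adjusted p = 0.0651). Without Selp high replicate 1 the priming medians were -0.04 and -0.05, without Selp high replicate 3 the lymphoid one was -0.07 and without Selp high replicate 2 the myeloid one was -0.11. Without Selp high replicate 4 the progenitor, lymphoid and myeloid medians were -0.62, -0.57 and -0.74. All 8 mitochondrially encoded genes had higher values in Selp high cells (median 0.57, camera adjusted p = 1.1e-04, 0.723 estimated), with mt-Nd2 at 262 ± 183 and 130 ± 81.5 CPM, and their median was 0.18 without Selp high replicate 4 (adjusted p = 0.0612). Type I interferon genes had a median of 0.09 (camera adjusted p = 0.0150, 0.847 estimated) and of -0.06 without Selp high replicate 2, 0.02 without Selp low replicate 4 and 0.04 without Selp low replicate 3.

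In this comparison edgeR called 0 of 16878 genes, and 863 had an unadjusted p under 0.05, where chance gives 844 for unpaired libraries. Of the 8 splits that part the libraries of every mouse, the real one had the most such genes (highest other 540, median 164). With 8 splits no share can fall under 0.05. Limma voom called 0 and DESeq2 11. Of the DESeq2 calls, Slc22a3, an organic cation transporter, Myc, Sox4 and the platelet glycoprotein gene Gp5 were lower and Jam2 was higher in Selp high cells. With the mouse as a block and only the pre-transplant libraries, edgeR called 2 genes, Slc22a3 (adjusted p = 0.0250) and Igkv14-126 (0.0384), both chosen after their values were seen. Slc22a3 was at 6.11 ± 2.03 CPM in Selp high and 27.7 ± 6.74 CPM in Selp low cells. By camera 9 lists were called, and 5 without Selp low replicate 4. No list kept its call with an estimated correlation or with fry, with smallest adjusted p-values of 0.723 and 0.704. None of the 11 marker lists of other cell types was called. Platelet-restricted genes had a median of 0.00, and Ppbp, a chemokine abundant in platelets, was at 1.08 ± 0.45 and 1.87 ± 0.15 CPM.

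The comparison after transplantation asked whether LT-HSCs derived from the 2 inputs differ when sorted without regard to P-selectin. Selp was at 301 ± 15.7 CPM in Selp high-derived (SD, n = 3) and 269 ± 23.7 CPM in Selp low-derived cells (SD, n = 3), a log2 difference of 0.16 ± 0.14 (edgeR adjusted p = 0.979). HSC ageing genes had list means of 5.64 ± 0.27 and 5.68 ± 0.26 log2 CPM, with 23 of 49 higher and 26 lower (camera adjusted p = 0.674). As lists, ribosomal protein, histone, myeloid priming and immediate early genes had lower values in Selp high-derived cells, and interferon gamma and MHC genes had higher ones, by camera with a preset correlation. None of these calls held with an estimated correlation (smallest adjusted p 0.367), and the immediate early median was 0.15 without Selp low-derived replicate 2. Several of these lists were at their highest in Selp low-derived replicate 2.

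Of 82 ribosomal protein genes, 79 had lower values in Selp high-derived cells (median -0.50, camera adjusted p = 4.4e-25, 0.777 with an estimated correlation). Their list mean was 7.36 log2 CPM in Selp low-derived replicate 2 and 6.24 to 6.68 in the other 5 libraries, and without that library the median was -0.17 (adjusted p = 7.7e-05). Rpl23 was at 72.2 ± 4.58 against 127 ± 68.8 CPM, which is uncertain because ribosomal genes have many processed copies. Nuclear OXPHOS genes had a median of -0.18 (camera adjusted p = 7.9e-06, 0.891 estimated) and mitochondrially encoded genes of -0.51 (0.0166, 0.891 estimated), with a list mean of 8.76 in Selp low-derived replicate 2 and 7.50 to 7.94 in the other 5. Without that library the OXPHOS, mitochondrially encoded and histone medians were -0.08 (adjusted p = 0.0345), -0.08 (0.821) and -0.15 (0.00961), and without Selp low-derived replicate 3 the OXPHOS one was -0.33. Of 34 histone genes, 27 had lower values (median -0.44, camera adjusted p = 7.9e-06, 0.367 estimated), and 2 were called adjusted over the list alone and 0 over all genes. Hist1h2ae was at 26.4 ± 7.87 against 55.0 ± 21.9 CPM and Hist1h4d at 23.3 ± 5.03 against 52.6 ± 21.3 CPM.

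Of 23 myeloid priming genes, 21 had lower values in Selp high-derived cells (median -0.80, camera adjusted p = 8.0e-06, 0.777 estimated). The transcription factor gene Cebpa was at 0.58 ± 0.24 against 1.35 ± 0.41 CPM and Elane, neutrophil elastase, at 44.1 ± 28.8 against 161 ± 22.5 CPM. Neutrophil markers had a median of -1.68 (camera adjusted p = 8.2e-06, 0.655 estimated), mast cell, basophil and eosinophil markers of -1.52 (4.3e-04, 0.655 estimated) and B cell markers of -0.95 (1.2e-04, 0.655 estimated). Without Selp low-derived replicate 2 the myeloid priming median was -0.51 (adjusted p = 0.00429) and those of the neutrophil and mast cell lists were -0.51 and -0.52, neither called. Without Selp high-derived replicate 3 the myeloid priming, mast cell and B cell medians were -1.22, -3.86 and -1.66. Immediate early genes, many of them transcription factors induced within minutes of a stimulus, had a median of -0.76 (camera adjusted p = 9.3e-05, 0.891 estimated), and 0.15 without Selp low-derived replicate 2. Fosb was at 1.22 ± 1.13 against 9.05 ± 12.7 CPM. Of 27 p53 targets, 21 had lower values (median -0.20, camera adjusted p = 0.00371, 0.367 estimated), with Zmat3, an RNA-binding protein gene, at 2.33 ± 0.76 against 5.37 ± 1.10 CPM and the death receptor gene Fas at 2.54 ± 1.42 against 5.25 ± 1.53 CPM, and their median was -0.11 without Selp low-derived replicate 2 and -0.38 without Selp low-derived replicate 1.

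Of 33 interferon gamma and MHC genes, 29 had higher values in Selp high-derived cells (median 0.18, camera adjusted p = 9.2e-04, 0.891 estimated), with the GTPase gene Gbp4 at 32.5 ± 7.19 against 20.4 ± 5.73 CPM. Cholesterol synthesis genes had a median of 0.14 (0.0323, 0.891 estimated), while the sterol carrier gene Stard4 had a lower value, at 70.7 ± 5.59 against 114 ± 3.03 CPM. S-phase (0.11), G2 and M-phase (0.16), quiescence (-0.23) and detoxification genes (-0.07) had camera adjusted p-values of 0.0323, 0.0413, 0.0299 and 0.0323 and estimated ones of 0.951, 0.951, 0.891 and 0.891. Without Selp low-derived replicate 2 the S, G2 and M, quiescence, cholesterol and detoxification medians were -0.08, -0.06, 0.01, 0.04 and -0.04, none called, and without Selp high-derived replicate 3 the G2 and M median was -0.08. Each of these lists, and the mitochondrially encoded one, also lost its call without at least 1 other post-transplant library, and the p53 targets without Selp low-derived replicate 3 (median -0.18, adjusted p = 0.0851). Kit, the stem cell factor receptor, was at 1415 ± 57.1 against 1069 ± 119 CPM. Here edgeR called 0 of 16878 genes, with 765 at an unadjusted p under 0.05, limma voom 1 (Adgrg7, named after its values were seen) and DESeq2 25, of which 3 were higher. None of the 13 lists kept its call with an estimated correlation (smallest adjusted p 0.367) or fry (0.348), and 7 lists were called without both post-transplant libraries that stood apart.

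The difference of the Selp effect between the stages was tested directly, and edgeR called 0 genes (874 at an unadjusted p under 0.05, DESeq2 11, limma voom 0). Myc differed by -0.74 before and, from 435 ± 54.6 against 399 ± 49.8 CPM, in the other direction after transplantation, a difference of 0.87 ± 0.20 on the log2 scale (edgeR adjusted p = 0.879). Jam2, at 51.8 ± 7.03 and 50.6 ± 16.6 CPM after transplantation, had a difference of -0.78 ± 0.26 and Flt3 of 1.69 ± 0.47, neither called. By camera, 11 of the 27 lists differed, among them G2 and M-phase genes (median 0.68, adjusted p = 1.6e-08) and HSC ageing genes (-0.19, 9.6e-04), each with an adjusted p of 0.861 with an estimated correlation. No list kept its call with an estimated correlation (smallest adjusted p 0.704). Without Selp high-derived replicate 3, 7 lists were called and the ageing median was -0.13 (adjusted p = 0.281). It was -0.12 without Selp low-derived replicate 2 and -0.31 without Selp low-derived replicate 1. The G2 and M median was 0.34 without Selp low replicate 4 and 0.45 without Selp low-derived replicate 2 or Selp high-derived replicate 3. Across 16878 genes, which are not independent replicates, the Selp differences before and after transplantation correlated with r = -0.03 and rho = -0.05, with r of -0.139 without Selp low replicate 4 and 0.059 without Selp high replicate 4. The 100 genes with the smallest p toward higher values before transplantation had a median of 0.01 after it (camera adjusted p = 0.957). The 100 toward lower values had a median of 0.11 (0.00338, 0.434 with an estimated correlation), with 31 keeping their direction.

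**Figure D2:**
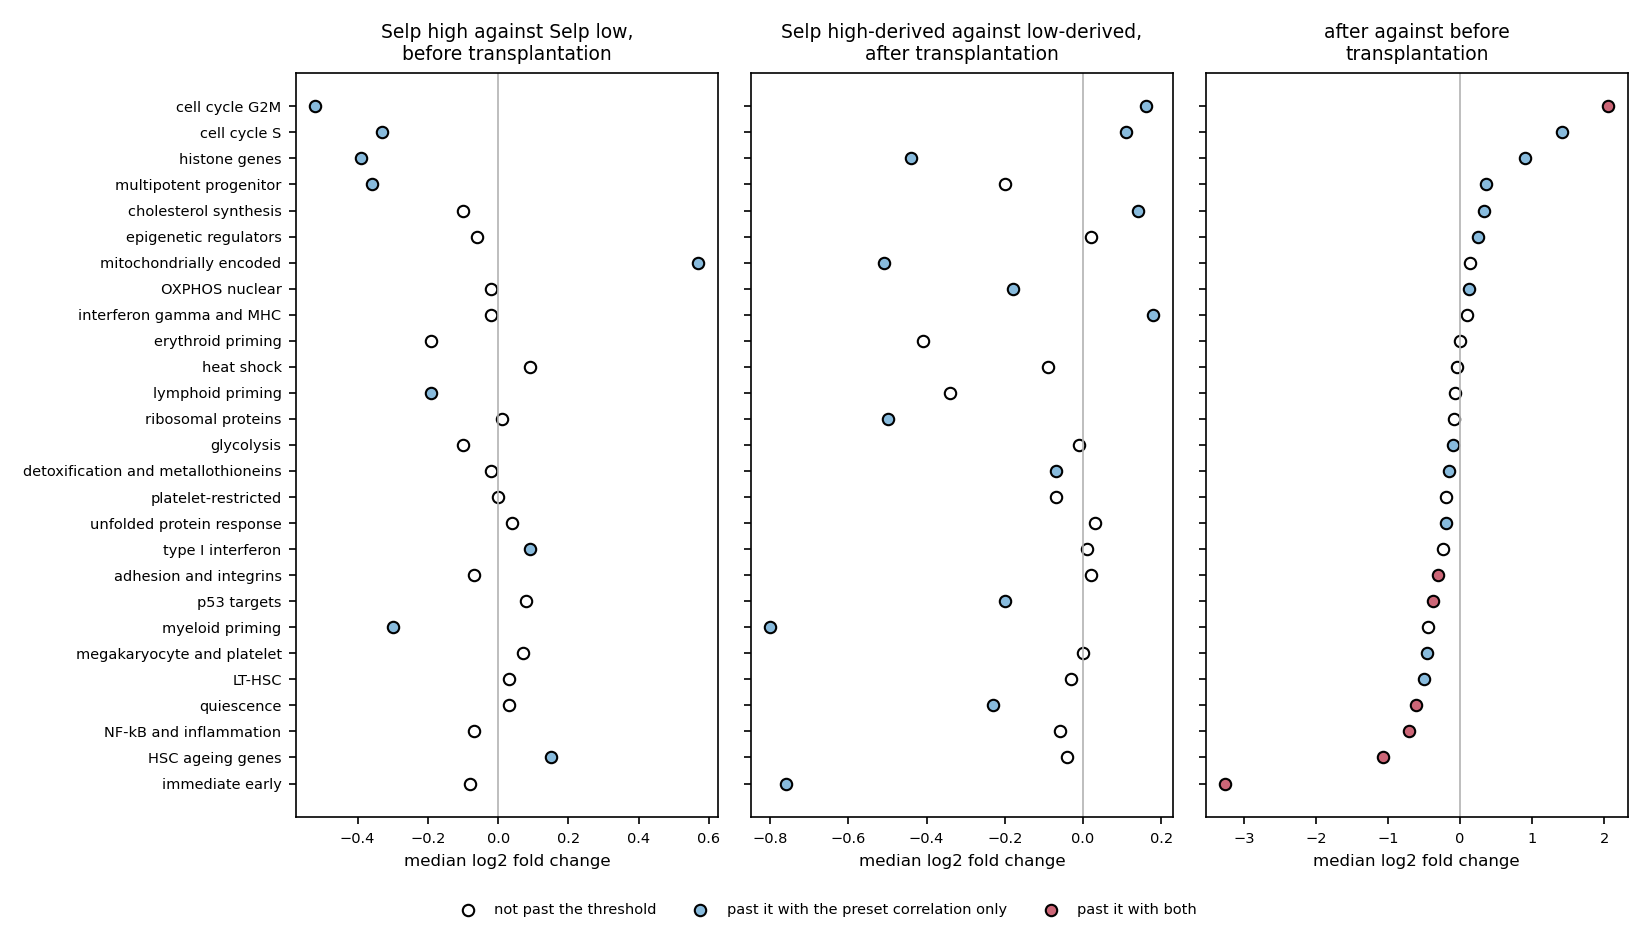
Median log2 fold change of the 27 gene lists for Selp high against Selp low cells before transplantation (left), Selp high-derived against Selp low-derived cells after it (middle) and after against before (right), each on its own scale. Blue points passed camera with the preset correlation alone and red points also with an estimated one, as for HSC ageing (-1.07) and immediate early genes (-3.26) on the right.

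The comparison of post-transplant with pre-transplant LT-HSCs described what differed in old donor cells after 16 weeks in young recipients. Recipient, irradiation, the CD45.2 gate and the day of collection changed with it, so none of these can be told apart. After transplantation, G2 and M-phase genes rose, while HSC ageing, immediate early, quiescence, NF-kB and p53 target genes fell, each also called with an estimated correlation (largest adjusted p 0.0489). Some of these lists share members, so their falls are not separate results. Egr1, Nr4a1 and Klf2 are in both the immediate early and quiescence lists, and Ier3 in both the immediate early and NF-kB lists. Cdkn1a is in both the quiescence and p53 target lists. S-phase genes rose with the preset correlation alone (adjusted p = 0.0503 with an estimated one). Selp fell by 1.15 ± 0.10 on the log2 scale (edgeR adjusted p = 3.5e-06), and its 6 post-transplant values, 243 to 315 CPM, lay below all 8 pre-transplant ones, 477 to 764 CPM. Slamf1 fell by 1.05 ± 0.10 (6.9e-06).

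Of 49 HSC ageing genes, 42 fell and 0 rose (median log2 change -1.07, camera adjusted p = 1.9e-45, 0.00527 with an estimated correlation), with 45 lower and 1 higher adjusted over the list alone. Endothelial markers, the only marker list called, had lower values too (median -1.67, 5 of 12 called lower, camera adjusted p = 0.00198, 0.412 with an estimated correlation). The list mean was 5.66 ± 0.24 after (SD, n = 6) and 6.98 ± 0.12 log2 CPM before transplantation (SD, n = 8, exact permutation p = 3.3e-04, the smallest 14 libraries taken as independent can give). Clu, a secreted chaperone, fell by 2.90 ± 0.17, and Itgb3, the integrin beta 3 subunit, by 2.72 ± 0.12, from 348 and 315 CPM in Selp low and Selp high cells to 41.8 and 60.5 CPM. Jam2 fell by 2.15 ± 0.14, the desmoglein gene Dsg2 by 2.16 ± 0.17, Mmrn1 by 0.80 ± 0.11 and Vwf by 0.85 ± 0.19. Of 32 long-term HSC genes, 21 fell and 0 rose (median -0.50, camera adjusted p = 7.5e-12, 0.0503 with an estimated correlation). Pdzk1ip1 fell by 1.18 ± 0.13 and Sult1a1, a sulfotransferase that the ageing list also holds, by 1.65 ± 0.19, while the abundant adhesion receptor gene Adgrg1 fell by 0.29 ± 0.07.

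All 38 G2 and M-phase genes rose (median 2.06, camera adjusted p = 7.4e-46, 0.0489 with an estimated correlation), as did 33 of 34 S-phase genes (median 1.42, 3.7e-33, 0.0503 estimated). The spindle checkpoint kinase gene Bub1b rose by 2.55 ± 0.26, Top2a, which untangles chromosomes, by 2.51 ± 0.27, Cdc20 by 1.74 ± 0.17, Cdt1 by 1.53 ± 0.15 and Mcm2 by 1.20 ± 0.13. Top2a was at 66.0 and 44.7 CPM in Selp low and Selp high cells and at 299 and 322 CPM in the cells derived from them. Of 34 histone genes, 14 rose and 2 fell (median 0.90, 3.4e-05, 0.0992 estimated). Of 24 quiescence genes, 16 fell and 2 rose (median -0.61, 1.3e-08, 0.0293 estimated). Among multipotent progenitor genes 8 rose and 1 fell (median 0.36, 0.00139, 0.353 estimated), with the surface sialomucin gene Cd34 up by 1.03 ± 0.14, Cdk6 by 1.36 ± 0.21 and the DNA ligase gene Lig1 by 1.58 ± 0.21.

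Of 30 immediate early genes, 29 fell (median -3.26, camera adjusted p = 2.2e-35, 0.0293 with an estimated correlation), with list means of 3.73 ± 0.80 after and 7.26 ± 0.49 log2 CPM before transplantation. Egr1 fell by 4.38 ± 0.39, Fos by 4.30 ± 0.98 and Ier2 by 2.81 ± 0.25. Of 30 NF-kB genes, 17 fell and 1 rose (median -0.71, 5.2e-07, 0.0489 estimated), with Ier3 at -2.66 ± 0.26 and Bcl3 at -1.34 ± 0.14. Of 27 p53 targets, 12 fell and 1 rose (median -0.38, 3.4e-05, 0.0335 estimated), with the cell cycle inhibitor gene Cdkn1a at -3.06 ± 0.39 and Perp, a desmosome gene, at -2.20 ± 0.20. Tissue dissociation and sorting also induce immediate early genes. Neutrophil markers had a median of -1.31 between the stages (camera adjusted p = 0.319).

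**Figure D3:**
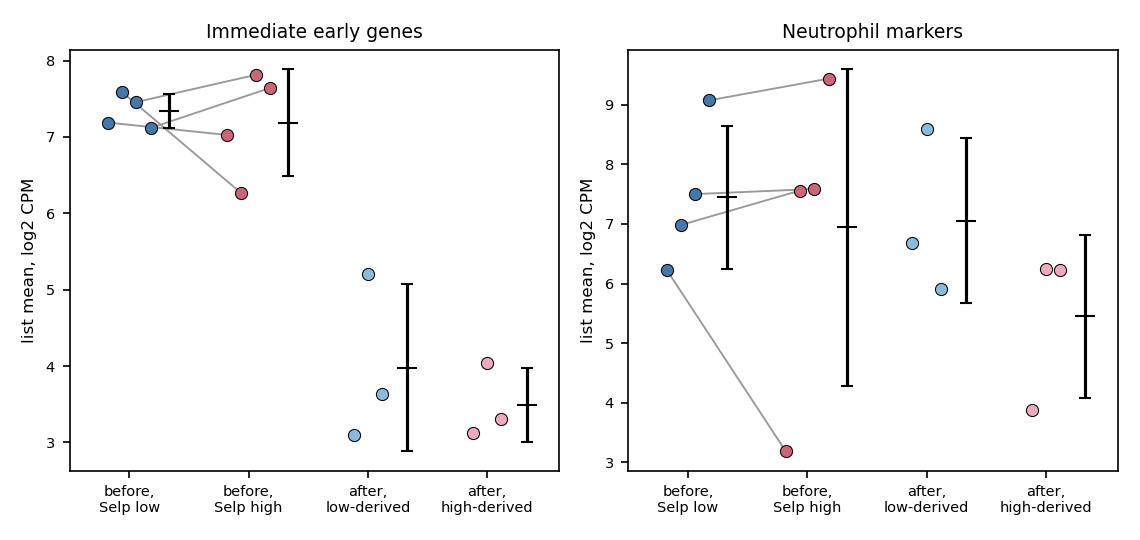
List means in log2 CPM of immediate early genes (left) and neutrophil markers (right) for each library (points), with group mean and SD (bars) and lines joining libraries of the same mouse before transplantation. All 8 pre-transplant libraries lie between 6.26 and 7.81 for immediate early genes and all 6 post-transplant ones between 3.09 and 5.20, while neutrophil values of the stages overlap.

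Adjusted over the list alone, 33 S-phase and 38 G2 and M-phase genes rose, while 23 long-term HSC, 16 quiescence, 29 immediate early, 17 NF-kB and 15 p53 target genes fell. Of 32 adhesion genes, 11 fell and 3 rose (median -0.31, camera adjusted p = 8.6e-05, 0.0293 with an estimated correlation). Of 26 megakaryocyte and platelet genes, 12 fell and 6 rose (median -0.46, 6.8e-04, 0.0503 estimated). Both lists share members with the HSC ageing list, so their falls are not separate from its fall. Itgb3, Jam2 and Dsg2 are among those shared with the adhesion list, and Itgb3, Mmrn1 and Vwf among those shared with the megakaryocyte and platelet list. The remaining lists called by camera had estimated adjusted p-values of 0.353 to 0.785: cholesterol synthesis (median 0.34, 7 rose, with Sqle up by 0.52 ± 0.12 and Stard4 by 0.72 ± 0.11), epigenetic regulators (0.25, 12 rose, 6 fell), nuclear OXPHOS (0.13, 5 rose, 1 fell), glycolysis (-0.10, 8 fell), detoxification (-0.15, 9 fell, 1 rose) and the unfolded protein response (-0.20, 9 fell). Among epigenetic regulators the DNA methylation genes Uhrf1 and Dnmt3b rose by 1.91 ± 0.21 and 0.84 ± 0.09 and the Polycomb gene Bmi1 fell by 0.73 ± 0.08, and the glucose transporter gene Slc2a3 fell by 1.01 ± 0.11. Without Selp low-derived replicate 2 the glycolysis median was -0.08 (adjusted p = 0.0553), without Selp low replicate 1 or Selp high replicate 4 the epigenetic one was 0.22 (0.0516) or 0.24 (0.0664), and the OXPHOS one lost its call, at medians of 0.09 to 0.12, without Selp low replicate 2 or 4, Selp high replicate 2, Selp low-derived replicate 1 or 2, or Selp high-derived replicate 3. The lists not called were erythroid (0.00), lymphoid (-0.07, with camera toward higher values) and myeloid priming (-0.45), platelet-restricted (-0.19, with a mean of 0.06), heat shock (-0.04), type I interferon (-0.24), interferon gamma and MHC (0.10), ribosomal protein (-0.08) and mitochondrially encoded genes (0.14). Of the marker lists, T cell (-0.94), B cell (-0.12), plasma cell (-0.21), monocyte and macrophage (0.16), dendritic (-0.67), NK (-2.55), mast cell, basophil and eosinophil (-0.32), erythroblast (-0.09, with a mean of 0.03) and stromal markers (-0.63) were not called.

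The 10 largest increases by the rule were Mc5r, a melanocortin receptor (3.75 ± 0.30 log2), Ccn3, a matricellular protein (3.10 ± 0.50), the kinesins Kifc1 (2.90 ± 0.40, uncertain because near-identical copies exist) and Kif18b (2.88 ± 0.25), Slc22a3 (2.78 ± 0.26), Pimreg (2.75 ± 0.34), Spsb4 (2.71 ± 0.27), Sapcd2 (2.62 ± 0.21), Ankle1 (2.60 ± 0.41) and the kinetochore gene Kntc1 (2.59 ± 0.28). The 10 largest decreases were Ccn1 (-7.75 ± 0.78), Atf3 (-7.69 ± 0.79), the imprinted Notch ligand-like gene Dlk1 (-6.06 ± 0.71), the nuclear receptor gene Nr4a1 (-5.76 ± 0.61), Ripk4 (-5.29 ± 0.53), Klf2 (-5.22 ± 0.50), the claudin gene Cldn5 (-5.21 ± 0.47), Cntn1 (-5.17 ± 0.53), Ptgs2, an inducible prostaglandin synthase (-4.91 ± 0.67), and the NF-kB regulator gene Nfkbiz (-4.86 ± 0.66). Mc5r was at 3.15 to 6.50 CPM as group means before and 60.6 to 61.5 CPM after transplantation, and Dlk1 at 35.2 to 41.6 and 0.38 to 0.86 CPM. All 20 had an edgeR adjusted p of 4.1e-04 or less and no overlap between the stages.

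In all, edgeR called 4631 of 16878 genes between the stages, 2175 higher and 2456 lower (DESeq2 5309, limma voom 6037). The share of higher calls was 47.0%, and 58.2% when libraries were scaled to their totals alone. Within Selp low 845 genes rose and 1091 fell, 1936 in all, and 803 in all without Selp low-derived replicate 1. Within Selp high 1287 rose and 1286 fell, 2573 in all, and 1423 in all without Selp high-derived replicate 3. Of these, 552 rose in both, where independent lists would share 64, and 713 fell in both, where they would share 83. These comparisons have no library in common. They do share the 4 mice, the fit, and the recipient, irradiation, gate and day that changed with the stage, so they are not independent. The 8 pre-transplant libraries came from 4 mice, and their pairing is not part of this test.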

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

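All tests of explanations in this part, and the counts of other splits of the libraries, were chosen after the results were seen. Of 290 groups of 4 values tested for a library far from the other 3, 26 had one, where chance gives about 14 (about 1 in 20), and 21 of the 26 were replicate 4 of a pre-transplant group, which is mouse 4. The 14 takes the groups as independent, while lists and genes overlap and some genes were named after their values were seen. The excess over 14 therefore decides nothing. Highest and lowest here refer to the 4 libraries of the same group only. Selp low replicate 4 had the highest list means of adhesion (6.00 log2 CPM), S-phase (5.57) and mitochondrially encoded genes (8.16) and the lowest of glycolysis genes (7.59). Selp high replicate 4 had the highest of T cell (1.11) and erythroblast markers (6.70), and Selp high replicate 3 the lowest of stromal markers (0.38). In CPM, Selp low replicate 4 was highest for S100a8 (3160.61), S100a9 (2854.10), mt-Nd2 (251.76), Mcm5 (201.34), Top2a (120.22), Uhrf1 (89.18), Igkv3-2 (39.21), Kif18b (22.63) and Igkv8-30 (1.21), and lowest for Eif2s3x (8.10). Selp high replicate 4 was highest for Igkv3-2 (18.26), Mc5r (6.46) and Igkv8-30 (0.24) and lowest for Jam2 (245.70) and Xist (2.77). Selp low replicate 2 was highest for Nr4a1 (1775.66) and Cdkn1a (84.56), and Selp high replicate 3 for Klf2 (635.02) and Bmi1 (134.20).

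The Selp difference after transplantation minus that before it was past the camera threshold for 12 lists, none of them with an estimated correlation. Its median was higher for G2 and M-phase (0.68), S-phase (0.45), cholesterol synthesis (0.22) and interferon gamma and MHC genes (0.20). It was lower for neutrophil markers (-1.99), mitochondrially encoded (-1.12), immediate early (-0.68), ribosomal protein (-0.54), p53 target (-0.34), HSC ageing (-0.19), nuclear OXPHOS (-0.17) and heat shock genes (-0.15). Without Selp low-derived replicate 2 the medians of neutrophil, immediate early, ribosomal protein, p53 target, nuclear OXPHOS and cholesterol genes were -0.74, 0.22, -0.18, -0.18, -0.07 and 0.09.

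Immediate early genes were lower after transplantation, with a list mean difference of -3.53 ± 0.37 log2 CPM (SE). RNA of neutrophils, which express such genes, is argued against as the cause, since neutrophil markers differed by -0.94 ± 0.92, less than such RNA would need. Toward it counts that Selp low-derived replicate 2 had the highest means of both lists after transplantation (8.59 and 5.20), and against it that Selp high replicate 1 had the lowest neutrophil mean (3.18) and an immediate early mean of 7.03. S100a8 was at 1240 and 1640 CPM in Selp low and Selp high cells and 1330 and 271 CPM in the cells derived from them. The Gr-1 and Mac-1 gate is meant to remove neutrophils, but these levels were found despite it, so it does not count against this cause. Longer or harsher handling of the pre-transplant cells may also induce these genes, and cannot be told apart from a change in the cells, since the days of sorting are confounded with the stage, with heat shock genes at a median of -0.04 (camera adjusted p = 0.0625) but list means of 6.11 ± 0.16 after and 6.59 ± 0.21 log2 CPM before transplantation (SD, exact permutation p = 0.00133), which goes toward it.

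HSC ageing genes were lower after transplantation, with a median of -1.07, as were endothelial markers (median -1.67, camera adjusted p = 0.00198, 0.412 with an estimated correlation). Fewer stem cells among the sorted cells could also lower ageing genes. The 23 long-term HSC genes outside the ageing and quiescence lists fell less, with a median of -0.34 (quartiles -0.61 and -0.23). This cannot decide, since how far each gene is limited to stem cells was not measured. Multipotent progenitor genes rose as a list with the preset correlation alone. This cannot tell fewer stem cells from more cells in cycle, since that list also holds genes of dividing cells, such as Cdk6 and Lig1. Endothelial cells carried along before transplantation could lower ageing genes as well. The 12 measured markers were lower by a median of 1.47 CPM (upper quartile 21.7, largest 85.6) and the ageing genes by 63.6 CPM (lower quartile 26.7). Most of these markers thus fell by fewer CPM than most ageing genes. This cannot decide, since the levels of ageing genes in endothelial cells were not measured. More cells in cycle may go with lower ageing genes, which cannot be told apart with this few libraries: across the 6 post-transplant ones, both groups together, the ageing and the G2 and M list means had r = -0.864 (exact permutation p = 0.0208, adjusted p = 0.0417 over 2 relations) and rho = -0.886 (exact permutation p = 0.0333, adjusted p = 0.0667). Centred within each group r was -0.875, and without the 2 libraries farthest from the median it was -0.837 over 4 libraries, too few to show that the relation holds without them. The other relation, within the pre-transplant libraries, covers 4 mice only, too few for an r, and with the 8 libraries taken as independent had an exact permutation p of 0.0499 (adjusted p = 0.0998) and a slope of -0.15 against -0.55 after transplantation, and the young recipient stays open and untested.

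Before transplantation Selp high cells had higher values of Selp (edgeR adjusted p = 0.957, not called) and of HSC ageing genes and lower ones of cell cycle genes, lists called by camera with a preset correlation but not with an estimated one (adjusted p = 0.723 for each) or fry. Attached platelets, which carry P-selectin, are argued against, since Ppbp differed by -0.79 ± 0.24 CPM (SE), and Pf4 by 2.38 ± 7.53 CPM, both far below the 135 ± 60.7 CPM by which Selp differed. More mature cells of other types among Selp low cells, which the gate on cells negative for lineage markers and CD48 is meant to remove, could change these lists. This cannot be told apart with this few mice, since 0 marker lists passed. Monocyte and macrophage markers had a median of -0.64 (camera adjusted p = 0.186). Within mice, T cell, NK, dendritic, erythroblast, endothelial and stromal list means were on average higher in Selp high cells, and those of the other marker lists lower. Endothelial list means were higher by 0.46 log2 CPM within mice (exact permutation p = 0.25, smallest possible 0.125). Endothelial cells among Selp high cells were not tested as a cause, and a difference between the cells sorted by P-selectin stays open.

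Other splits of the libraries into groups of the same sizes were fitted in the same way. Between the stages and for the difference, the 50 splits were the real one and others drawn at random from those possible. None of the others drawn gave as many genes between the stages, with 4631 in 1 of 50, the real one (highest other 3390). With all splits of the 7 libraries of a Selp group, the same held within Selp low (1 of 35, 1936 genes, highest other 1647) and Selp high (1 of 35, 2573, highest other 635). Splits exchange single libraries, though pre-transplant libraries came in pairs from 4 mice and separate recipients are not given. These shares alone therefore do not exclude chance. The highest others within Selp low and within Selp high set pre-transplant replicates 1, 2 and 3 against all other libraries of the Selp group, which nearly parts the stages. Chance can explain the correlation across genes of size 0.03 (30 of 50, highest other 0.157). Counts of lists by camera with the preset correlation are high under most splits and decide nothing, with 18 lists between the stages (7 of 50 splits, highest other 20, median 13), 9 before transplantation (25 of 35, highest other 16, median 10.5) and 11 for the difference (23 of 50, highest other 18, median 10). Between the stages 17 of 27 list means had an unadjusted exact permutation p under 0.05 (smallest 3.3e-04, the smallest possible), though with the 8 pre-transplant libraries taken as independent. Every split reaches 0 genes, so the counts before transplantation (35 of 35 splits) and for the difference (50 of 50, highest other 0) say nothing on chance. Before transplantation the highest other split, 91 genes for mice 3 and 4 against mice 1 and 2, points to a structure by mouse. Among the 8 splits that part every pair of libraries of a mouse, 3 gave at least 9 lists (highest other 11) and 1, the real one, gave 863 genes at an unadjusted p under 0.05 (highest other 540, median 164). These 8 splits cannot give a share under 0.05 either way. After transplantation 10 splits are too few for a share under 0.05, with 0 genes in 10 of 10 (highest other 0) and 13 lists in 2 of 10 (highest other 13).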

How the results depend on the processing

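Besides the alternatives set beforehand, the block before transplantation only, the block with only the pre-transplant libraries, mouse 4 left out, the 2 post-transplant libraries that stood apart left out and the pairs of estimated correlation and block were chosen after seeing the data. The count between the stages, 4631, was 3688 to 5022 with 1 library left out and 4099 to 6037 otherwise, and shared 77.2 to 99.4% of the genes. Before transplantation the 0 genes became 1 with no filter, 11 with DESeq2 and 2 with the replicate block and only the pre-transplant libraries, and 0 to 2 with 1 library left out (2, Jam2 and Slc22a3, without Selp low-derived replicate 1). After transplantation the 0 genes became 25 with DESeq2, 1 with voom, 2 with the block within each stage, 1 with the block before transplantation only and 1 without mouse 4, and stayed at 0 to 0 with 1 library left out. For the difference they became 11 with DESeq2. The lists called, 9 before transplantation, 13 after it and 11 for the difference, became 0 with an estimated correlation, 0 with fry and 0 with an estimated correlation and any block, and the 18 between the stages became 7 with an estimated correlation. With 1 library left out they were 5 to 13, 9 to 15, 7 to 12 and 17 to 19, and without the libraries that stood apart the 13 became 7. The correlation of -0.03 was -0.082 with voom and -0.139 to 0.059 with 1 library left out. With 1 library left out, list medians before transplantation ran from -0.57 to 0.01 for lymphoid priming, -0.74 to 0.18 for myeloid priming (both highest without Selp low replicate 4) and -0.06 (without Selp high replicate 2) to 0.21 for type I interferon genes. After it they ran from -0.08 to 0.40 for S-phase, -0.08 to 0.49 for G2 and M-phase, -0.32 to 0.01 for quiescence and -1.06 to 0.15 for immediate early genes, and -0.92 to 0.22 for immediate early genes of the difference. Without the libraries that stood apart these were -0.09, -0.06, 0.01, 0.22 and 0.40. The cause was not tested, except that an estimated correlation widens the test by construction. What depth limits was not tested, and simulated data at these depths and group sizes called 62 to 71 of 100 genes changed 2-fold, all with a mean log2 CPM of at least 1.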

Other observations

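The hypothesis on the X chromosome in this part was tested only after the result was seen. Megakaryocyte and platelet genes moved apart between the stages. The platelet alpha granule chemokine genes Ppbp and Pf4 rose by 2.51 ± 0.23 and 2.32 ± 0.33 on the log2 scale (SE, edgeR adjusted p = 5.8e-06 and 1.6e-04) and the glycoprotein gene Gp5 by 1.24 ± 0.18 (1.9e-04). The receptor gene Clec1b fell by 2.79 ± 0.31 (2.6e-05), as did Itgb3, by 2.72 ± 0.12. Pf4 was at 13.4 and 15.8 CPM in Selp low and Selp high cells and at 93.3 and 56.8 CPM in the cells derived from them. Histone genes also parted, with Hist1h2ae up by 2.09 ± 0.18 and the linker histone gene Hist1h1c, whose transcripts can be polyadenylated, lower at -1.33 on the log2 scale.

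Xist, the RNA that silences an X chromosome in female cells, fell by 3.24 ± 0.87 between the stages (edgeR adjusted p = 0.0132). It was at 17.54 to 36.07 CPM in both libraries of mice 1 to 3, at 1.63 and 2.77 CPM in mouse 4 and at 0.18 to 8.59 CPM after transplantation, and reads of its antisense gene cannot be told apart without strand. Loss of the inactive X chromosome in part of the cells may lower it, and would also lower genes that escape silencing. The median of 4 such genes was -0.49, with Kdm6a (-0.78, adjusted p = 0.00249) and Ddx3x (-0.63, 2.7e-04) called and Eif2s3x (-0.36, 0.139) and Kdm5c (-0.13, 0.416) not called, so this stays open. Among genes with a mean log2 CPM of at least 4, 259 X-linked ones had a median of 0.00 (quartiles -0.26 and 0.15) and 8381 autosomal ones of 0.00 (quartiles -0.20 and 0.21).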
